A study of Shewanella oneidensis MR-1 with 6 samples.

How the data were processed

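RNA was sequenced from anode-harvested cells of Shewanella oneidensis MR-1, with 3 libraries of the engineered strain SDV3 and 3 of the wild type (WT). Per the labels, cells were collected by centrifugation and frozen in liquid nitrogen, RNA was isolated with a RNAprep pure Cell/Bacteria kit and libraries were made with a NEBNext Ultra RNA kit for Illumina sequencing. The aligner, the counting tool, the genome build and the use of strand in counting are not given in the sources used here. The authors' deposited table holds 4856 features of a single chromosome sequence, of which 4438 are annotated genes, 371 are predicted transcripts outside the annotation and 47 are named sRNA. Per the file headers, it gives a count and an FPKM value for each feature and library. The deposited table also gives size-factor-scaled values (each count divided by a constant per library, from the values), and a log2 fold change, a p-value and an adjusted p-value of SDV3 against WT by the authors. In the authors' columns 77 features hold no value and 13 p-values are missing. The feature length in bases is deposited too.

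The libraries held 5055515 to 5528921 counts, with 2.86% to 3.32% on unannotated and sRNA features except for 6.79% in SDV3-3. At this depth the self-test described here gives the precision for changes of a given size in simulated libraries.

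Identifiers of the table matched 0 of the 4629 entries of the reference gene table, so gene symbols came from the deposited table (1176 genes) and from its protein descriptions (1278 genes with a symbol after that step). Genes without a unique symbol are printed by identifier. Only 60 genes carried a locus tag of the older MR-1 annotation. Of the 31 gene lists fixed before the data were examined, 26 had at least 5 members in the table and 5 had 0: the lists for 3 prophages, the megaplasmid and the introduced phenazine and transport genes. From annotation alone, the Mtr list was completed with genes of the same families near omcA, and genes of other functions were taken out of the tRNA and rRNA list and the iron list.

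Counts of annotated genes were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 4165. Library sizes were scaled by TMM, with factors of 0.844 to 1.29. The quasi-likelihood F test compared the strains with no block, since the labels give no batch and the library numbers do not pair the samples. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and a second count required an absolute log2 fold change of at least 1. The SE of a log2 fold change was taken as its absolute value over the square root of F. CPM values use the TMM-scaled library sizes. Lists with at least 5 tested members were tested by camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 26 lists. Members were also adjusted over their list alone. Principal components and Pearson correlations used the same log2 CPM. Runs of called genes were neighbours among the called genes on a single strand, changed in the same direction and at most 300 bases apart. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

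The named genes were fixed by rule before the data were examined. They are the 10 largest increases and the 10 largest decreases among called genes with separate values between strains and a mean of at least 20 CPM, up to 4 called members of each list with the same minimum, and mtrA, the mtrB-like gene HRJ35_RS10735, mtrC, omcA and cymA in every case. This gave 30 genes, 25 called and 5 not. Other genes in the report, given with values of list members or neighbours, were chosen after their values were seen.

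The fit was tested on simulated data with the counts, library sizes and dispersions of the real libraries and 200 changed genes. At the real dispersion, 11 of 49 genes changed by 1 on the log2 scale were called, 45 of 49 changed by 2, and 100 of 100 changed by 4, with 5 of 3942 unchanged genes called. Changes near 1 on the log2 scale are therefore mostly missed.

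Each result was recomputed under 15 alternatives fixed before the data were examined. These were DESeq2 1.42.0, limma on log2(FPKM + 1) and on log2(FPKM + 0.1) for genes with a mean FPKM of at least 1, DESeq2 size factors or upper quartile factors in edgeR, no low-count filter, a mean of at least 10 CPM, the library number as a block, each of the 6 libraries left out, and tRNA and rRNA genes left out. A planned quantile normalization applied only to a table without counts and was not run. Camera was also run with an estimated correlation. A further 3 alternatives were chosen after seeing the data: unannotated and sRNA features included, the small stable RNA genes ssrA, rnpB and ffs left out with tRNA and rRNA, and a robust quasi-likelihood fit. Unannotated and sRNA features were left out of the comparison because 407 of them overlap annotated genes, all on the opposite strand.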

Results

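RNA was sequenced from Shewanella oneidensis MR-1, a bacterium that passes respiratory electrons to solid acceptors outside the cell. The engineered strain SDV3 was compared with the wild-type strain (WT). Cells of both strains had been harvested from the anode of an electrode system. The title of the study concerns making and exporting phenazine-1-carboxylic acid, a diffusible redox compound that can carry electrons out of the cell. Each strain had 3 libraries, numbered 1 to 3. Nothing in the labels says that the libraries of a strain came from separate cultures, so the p-values measure the spread between these libraries, which may be technical in part. The libraries held 5055515 to 5528921 counts over 4856 features, of which 4438 were annotated genes. The list of introduced phenazine and transport genes matched 0 genes by symbol, and the introduced genes were therefore not analysed here.

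The comparison of SDV3 with WT asks how the transcriptome of the engineered strain on the anode differs from that of its parent. The sulfite reductase gene sirA and the thiosulfate reductase gene phsA were higher in SDV3, at 22.9-fold and 12.9-fold, each with called neighbours. A TolC family outer membrane protein and its neighbouring RND adaptor were also higher, as were the methionine synthesis genes metB and metE. The catalase/peroxidase gene HRJ35_RS06005 and the alkyl hydroperoxide reductase gene ahpF were lower in SDV3, at 11.2-fold and 4.84-fold. A polysaccharide and efflux region of 7 called genes was also lower. In total 40 of 4165 tested genes passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 20 higher and 20 lower in SDV3. All 40 had an absolute log2 fold change of at least 1. Of the 40, 22 lay in 9 runs of neighbouring genes on a single strand.

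The sulfite reductase run lay on the plus strand at 1092618 to 1096924 and held 4 called genes. sirA, the octaheme cytochrome c that reduces sulfite, had 481 ± 299 CPM (SD, n = 3) in SDV3 and 21.0 ± 3.36 CPM (SD, n = 3) in WT, a log2 fold change of 4.51 (SE 0.60, edgeR adjusted p = 0.0160). HRJ35_RS04875, a rhodanese-like protein, had the largest fold change of the called genes, at 5.22 on the log2 scale (SE 0.57, edgeR adjusted p = 0.00845). Its WT level was only 1.24 ± 0.281 CPM (SD, n = 3), against 46.8 ± 24.2 CPM in SDV3. The tetratricopeptide repeat gene HRJ35_RS04885 and the FKBP-type isomerase gene HRJ35_RS04880 rose by 4.67 and 4.32 on the log2 scale. The phs run, on the minus strand at 4805086 to 4808894, held 3 called genes. phsA, the catalytic subunit of thiosulfate reductase, had 546 ± 177 CPM (SD, n = 3) in SDV3 and 42.3 ± 13.3 CPM (SD, n = 3) in WT, a log2 fold change of 3.69 (SE 0.38, edgeR adjusted p = 0.00804). Its iron-sulfur neighbour HRJ35_RS21505 and the NrfD family membrane subunit HRJ35_RS21500 rose by 4.23 and 3.63 on the log2 scale. sirA, phsA and HRJ35_RS21500 belong to the list of anaerobic terminal reductases, in which 3 of 25 tested members rose, 0 fell and 22 did not pass (12 higher when adjusted over the list alone). The list stood higher than the other genes (camera adjusted p = 1.87e-05 with a preset correlation), a call lost at adjusted p = 0.657 with an estimated correlation. Without SDV3-3, 10 members of the list rose. That fit called 1327 of 4207 tested genes, 711 higher and 616 lower, and all list counts without SDV3-3 are to be read beside this share. Other members with large mean changes did not pass. napA, the catalytic subunit of periplasmic nitrate reductase, had a log2 fold change of 4.52 (SE 1.13, edgeR adjusted p = 0.0940), with 263, 941 and 5229 CPM in the SDV3 libraries and 40.1 to 166 CPM in WT. nrfA, the nitrite reductase that forms ammonia, had 2.73 (SE 0.81, edgeR adjusted p = 0.125).

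**Figure D1:**
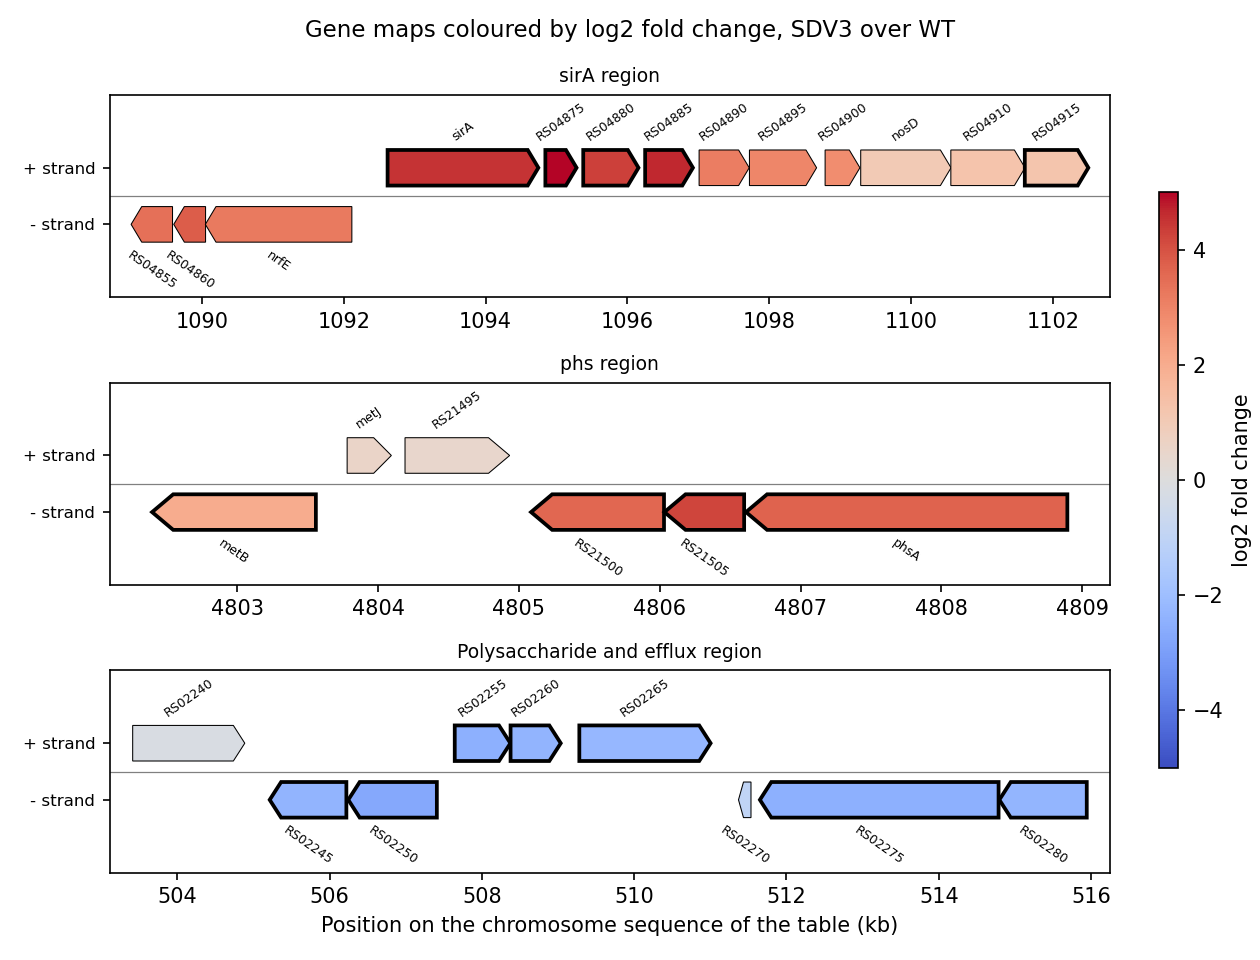
Gene maps of 3 regions by position in kb, with each gene coloured by its log2 fold change in SDV3 over WT and a thick outline for genes past an adjusted p of 0.05. The sirA and phs runs are higher in SDV3, and the polysaccharide and efflux region at 505214 to 515943 is lower.

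Among the oxidative stress genes 2 were lower in SDV3. HRJ35_RS06005, a catalase/peroxidase of the KatG type at 1329661 to 1331886, had 132 ± 49.1 CPM (SD, n = 3) in SDV3 and 1478 ± 195 CPM (SD, n = 3) in WT, a log2 fold change of -3.49 (SE 0.34, edgeR adjusted p = 0.00804). ahpF, which passes electrons to alkyl hydroperoxide reductase, fell by 2.27 on the log2 scale (SE 0.31, edgeR adjusted p = 0.0179). Of the 12 tested oxidative stress genes, 2 fell, 0 rose and 10 did not pass (6 lower and 1 higher when adjusted over the list alone). katB and ahpC had log2 fold changes of -2.32 and -2.20 with edgeR adjusted p of 0.0555 and 0.0598. Without SDV3-3, 6 genes of the list fell. The other catalase/peroxidase gene of this type, HRJ35_RS00925, had 0.05, and the regulator oxyR had -0.02. The list was lower than the other genes (camera adjusted p = 0.000105), a call lost at adjusted p = 0.657 with an estimated correlation.

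Transport and export genes changed in both directions. Of the 50 tested efflux genes (RND, MATE, TolC and related families), 3 rose, 3 fell and 44 did not pass, with 9 higher and 6 lower when adjusted over the list alone. Without SDV3-3, 14 rose and 12 fell, in a fit that called 1327 of 4207 tested genes. The TolC family gene HRJ35_RS05050 and the RND periplasmic adaptor gene HRJ35_RS05055, neighbours on the plus strand at 1130196 to 1132861, rose by 2.74 (SE 0.46, edgeR adjusted p = 0.0408) and 2.37 (SE 0.30, edgeR adjusted p = 0.0129) on the log2 scale. HRJ35_RS05050 had 208, 269 and 76.6 CPM in SDV3-1, SDV3-2 and SDV3-3, and its call was lost in 5 of the 6 leave-one-out fits. tolC itself, the outer membrane channel shared by several export systems, fell by 1.38 (SE 0.23, edgeR adjusted p = 0.0380). The RND permease gene HRJ35_RS02275 and its adaptor gene HRJ35_RS02280 fell by 2.47 and 2.31 on the log2 scale. In the same region lie HRJ35_RS02250, a nucleotide sugar dehydrogenase gene, and HRJ35_RS02255, a glycosyltransferase gene, which fell by 2.73 and 2.47, and HRJ35_RS02260, which fell by 2.36. HRJ35_RS05080, an HlyD family secretion gene, was 10.1-fold lower in SDV3 (log2 fold change -3.33, SE 0.48, edgeR adjusted p = 0.0218). The direction of the efflux list as a whole did not differ from the other genes (camera adjusted p = 0.660).

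Outside these lists, HRJ35_RS18340, a cytochrome b gene, had the smallest adjusted p of all genes. It had 14.5 ± 2.70 CPM (SD, n = 3) in SDV3 and 140 ± 17.1 CPM (SD, n = 3) in WT (log2 fold change -3.27, SE 0.24, edgeR adjusted p = 0.00382). Its neighbour HRJ35_RS18335, of the YceI family, fell by 3.10 on the log2 scale. HRJ35_RS10650 and HRJ35_RS10645, neighbours on the plus strand at 2430449 to 2431411, fell by 2.99 and 2.98. Among the higher genes, the TRAP transporter small permease gene HRJ35_RS17230 rose by 2.77 on the log2 scale (SE 0.46, edgeR adjusted p = 0.0396), a call lost in 5 of the 6 leave-one-out fits. HRJ35_RS10200, which encodes a GGDEF domain protein, rose by 2.59 (SE 0.30, edgeR adjusted p = 0.0111). Proteins with this domain commonly make the second messenger cyclic di-GMP. In the list for sulfate assimilation, cysteine and methionine, 2 of 27 tested genes rose, 0 fell and 25 did not pass (3 higher when adjusted over the list alone). Without SDV3-3, 7 rose and 4 fell, in a fit that called 1327 of 4207 tested genes. With all libraries the called genes were metB, for cystathionine gamma-synthase, with a log2 fold change of 2.00 (SE 0.22, edgeR adjusted p = 0.00845), and metE, for the cobalamin-independent methionine synthase, with 1.30 (SE 0.20, edgeR adjusted p = 0.0311). The list itself did not pass (camera adjusted p = 0.154).

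**Figure D2:**
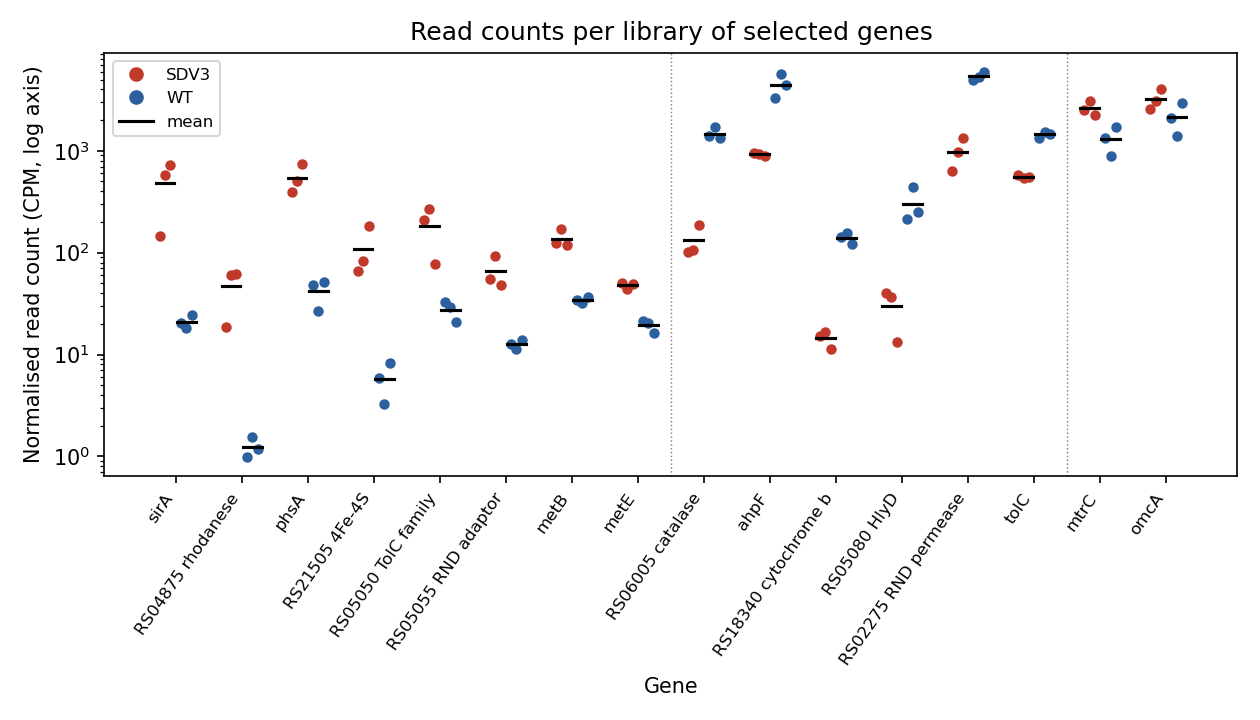
Normalised read counts (CPM, log axis) of 16 genes in each SDV3 library (red) and WT library (blue), with a black line at each strain's mean of 3 libraries. The left 8 genes are higher in all SDV3 libraries, the middle 6 are lower, and the SDV3 and WT values of omcA overlap while those of mtrC do not.

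The Mtr pathway carries electrons across the outer membrane. With all libraries the edgeR test without a block called its genes in neither direction. mtrC, the outer surface decaheme cytochrome, had 2614 ± 411 CPM (SD, n = 3) in SDV3 and 1318 ± 418 CPM (SD, n = 3) in WT, a log2 fold change of 0.99 (SE 0.33, edgeR adjusted p = 0.142). omcA had a log2 fold change of 0.58 (SE 0.36, edgeR adjusted p = 0.358) and mtrA had 0.74 (SE 0.29, edgeR adjusted p = 0.201). HRJ35_RS10735, the MtrB/PioB family gene next to mtrA, had 0.64, and cymA, the inner membrane quinol dehydrogenase, had 0.38. All 8 tested members had positive fold changes and 0 passed, also when adjusted over the list alone. Apart from cymA, the members carry consecutive identifiers and may change together, so they are not separate observations. As a list they stood higher than the other genes (camera adjusted p = 0.00873), a call lost at adjusted p = 0.657 with an estimated correlation. The list also missed the threshold without SDV3-3 (camera adjusted p = 0.0563) and without WT-2 (camera adjusted p = 0.0682). Without SDV3-3, 2 of the 8 passed, both higher: mtrC (edgeR adjusted p = 0.0337) and HRJ35_RS10765, a DmsE family decaheme cytochrome gene. mtrC also passed in the authors' deposited table (adjusted p = 0.0366).

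Some lists of central energy metabolism and translation were lower in SDV3 as lists with the preset correlation only, with 0 members past the threshold over all genes. Their calls were lost with an estimated correlation, at adjusted p = 0.657 to 0.674. Many members carry consecutive identifiers, such as the 8 ATP synthase genes and nuoA to nuoN, and neighbours may change together. Counts of members in 1 direction are then not separate observations, and the preset correlation of 0.01 may be too low. The lists for lactate, pyruvate and acetate and for the pentose phosphate pathway did not pass (camera adjusted p = 0.220 and 0.102). Nor did those for aerobic oxidases and for formate and hydrogen oxidation (camera adjusted p = 0.445 and 0.662). Of the 10 aerobic oxidase genes, though, 3 rose and 4 fell when adjusted over the list alone. Without SDV3-3, 2 of them rose and 4 fell over all genes. Camera tests the direction of a list as a whole and does not show such opposed changes. Without SDV3-3 the edgeR test called 10 of the 12 genes of the tricarboxylic acid and glyoxylate list lower and 1 higher. It also called 16 of 18 NADH dehydrogenase, 43 of 54 ribosomal protein and 6 of 8 ATP synthase genes lower. Over all genes that fit called 616 of 4207 lower. Of the 12 genes of the tricarboxylic acid and glyoxylate list, 10 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.000104, and adjusted p = 0.657 with an estimated correlation). The 10 include prpC and acnD, annotated as 2-methylcitrate synthase and 2-methylisocitrate dehydratase rather than as tricarboxylic acid or glyoxylate enzymes. mdh, for malate dehydrogenase, had a log2 fold change of -1.70 (SE 0.31, edgeR adjusted p = 0.0537) and sdhA had -1.12 (edgeR adjusted p = 0.128). SDV3-3 lay between the other SDV3 libraries and WT for sdhA, at 1557 CPM against 772 and 825 CPM in SDV3-1 and SDV3-2 and 2145 to 2485 CPM in WT. The glyoxylate genes aceA and aceB had 0.92 and 0.63. Of the 18 NADH dehydrogenase genes, 16 had negative fold changes and 3 fell when adjusted over the list alone (camera adjusted p = 0.000128, and adjusted p = 0.657 with an estimated correlation). Of the 54 ribosomal protein genes, 51 had negative fold changes, with a list median of -0.69 (-1.18 without SDV3-3), and 0 passed when adjusted over the list alone (camera adjusted p = 5.45e-11, and adjusted p = 0.657 with an estimated correlation). Ribosomal protein genes took 12.8%, 12.2% and 17.9% of all counts in SDV3-1, SDV3-2 and SDV3-3, and 18.3% to 21.9% in WT. All 8 ATP synthase genes had negative fold changes (camera adjusted p = 0.0398, and adjusted p = 0.674 with an estimated correlation). That call was lost without SDV3-1 (adjusted p = 0.247), SDV3-2 (adjusted p = 0.0929) or WT-3 (adjusted p = 0.149), with a filter at a mean of 10 CPM (adjusted p = 0.0510) and with limma on log2(FPKM + 0.1) (adjusted p = 0.0503). Of the 18 heat shock and chaperone genes, 12 had negative fold changes and 1 fell when adjusted over the list alone (camera adjusted p = 0.00141, and adjusted p = 0.657 with an estimated correlation). htpG had a log2 fold change of -1.50 (edgeR adjusted p = 0.0752) and groL had -1.13 (edgeR adjusted p = 0.127). This list missed the threshold without SDV3-3 (camera adjusted p = 0.0563), where 7 members fell and 1 rose, with a list median of -0.50 against -0.60.

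The flagellar genes stood higher as a list (camera adjusted p = 0.000661, and adjusted p = 0.657 with an estimated correlation). Of its 36 members, 34 had positive fold changes, with a list median of 0.38, and 0 passed over all genes or when adjusted over the list alone. Many of the members lie in runs of nearly consecutive identifiers and may change together. fliD, the filament cap gene, had a log2 fold change of 1.06 (edgeR adjusted p = 0.105). Without SDV3-3 the list missed the threshold (camera adjusted p = 0.143), with 4 members higher, 1 lower and a list median of 0.18. The tRNA and rRNA genes, kept as a list for RNA quality, stood higher too (66 of 70 with positive fold changes, 0 past the threshold over all genes or adjusted over the list alone, camera adjusted p = 9.22e-06, and adjusted p = 0.657 with an estimated correlation). tRNA genes took 0.649%, 0.367% and 0.148% of all counts in SDV3-1, SDV3-2 and SDV3-3, and 0.105% to 0.291% in WT. Without SDV3-3, 14 of the tRNA and rRNA genes rose and 1 fell. In total 10 of 26 lists with at least 5 tested members passed with the preset correlation, 4 higher and 6 lower in SDV3. Of the 10 splits of the 6 libraries into 3 and 3, 4 gave at least as many lists, the real split among them, and the highest other gave 13. None of the 10 calls held with an estimated correlation, at camera adjusted p = 0.657 for 9 lists and adjusted p = 0.674 for ATP synthase. In that fit 0.657 was the lowest adjusted p of all 26 lists and was shared by lists not called here. It therefore did not tell the called lists from the others. The other 16 lists had camera adjusted p of 0.0867 to 0.863 with the preset correlation.

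**Figure D3:**
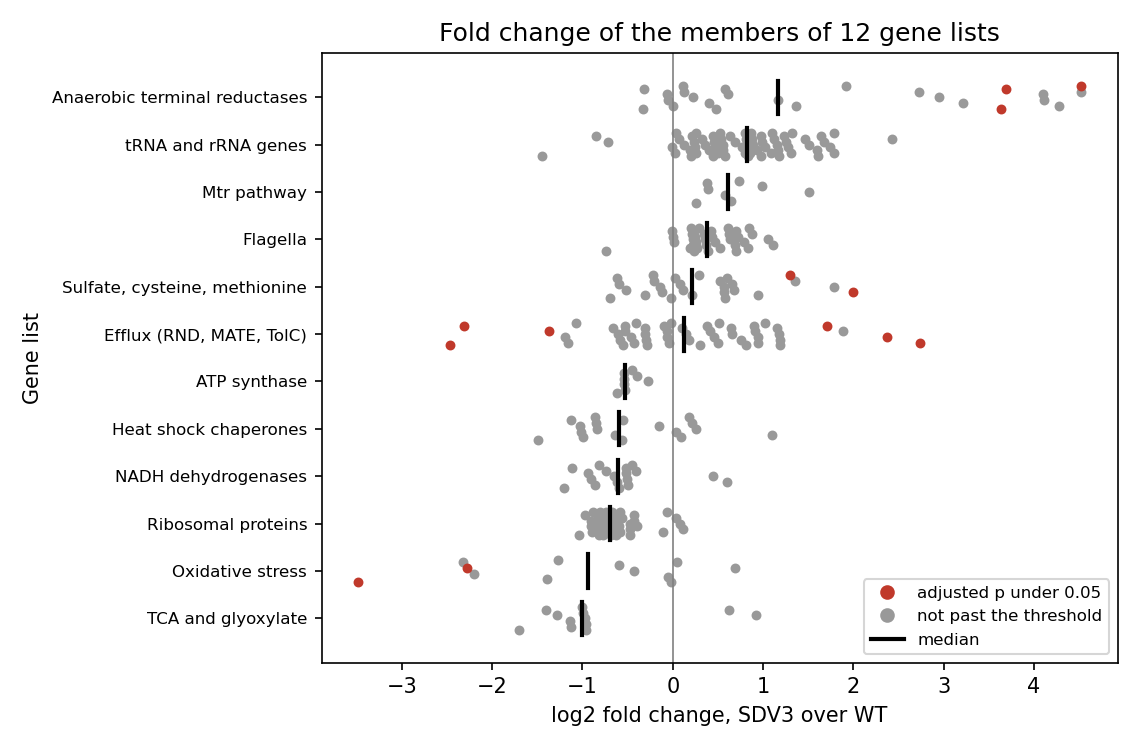
Log2 fold changes (SDV3 over WT, horizontal axis) of the tested members of 12 gene lists, with a black bar at each list's median and red points for genes past an adjusted p of 0.05. The lowest list median is that of the tricarboxylic acid and glyoxylate genes, and the highest, 1.17, that of the anaerobic terminal reductases.

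SDV3-3 lay apart from the other SDV3 libraries. The leading principal component took 55.7% of the variance of log2 CPM and placed SDV3-1 and SDV3-2 at -37.3 and -34.9, SDV3-3 at 11.1 and the WT libraries at 19.5 to 21.6. Across genes, SDV3-3 correlated with SDV3-1 and SDV3-2 at Pearson r = 0.904 and 0.918 and with WT-1, WT-2 and WT-3 at 0.951, 0.929 and 0.949, while the r between SDV3-1 and SDV3-2 was 0.982 and the WT libraries reached 0.957 to 0.978 with each other. SDV3-3 also had 6.79% of its counts on features that are not annotated genes (2.86% to 3.32% in the others), 2.60% on rnpB (0.626% to 1.04% in the others) and 4.53% on ssrA (1.63% to 3.53% in the others). Without SDV3-3 the edgeR test called 1327 genes, 711 higher and 616 lower, against 40 with it. It called 11 without SDV3-2, 2 without WT-1, 7 without WT-2 and 2 without WT-3, with 23 of the 25 named genes past the threshold losing their call in at least 1 of these fits. DESeq2 called 463 genes, 296 higher and 167 lower, and limma on log2(FPKM + 1) called 34, 13 higher and 21 lower. The 40 calls kept their direction in these fits, and all 40 were among the 243 higher and 180 lower annotated genes of the authors' deposited table, in the same direction. The fits and the authors' values rest on the same counts, so neither is independent support. Of the 40 genes, 11 overlap a feature that is not an annotated gene and 2 overlap another annotated gene, HRJ35_RS05080 among the former. Whether reads were counted by strand is not stated, and the library kit is not stated to be directional, so the counts of these genes are uncertain. The values of the 40 genes did not overlap between strains, but these genes were selected by the same comparison, so this adds no support. Of all tested genes, 26.0% had values that did not overlap. The average over the 10 splits of the libraries is 10%, but genes that change together can raise the share of a single split. The share was not computed for the other splits, so 26.0% was not tested against chance.

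**Figure D4:**
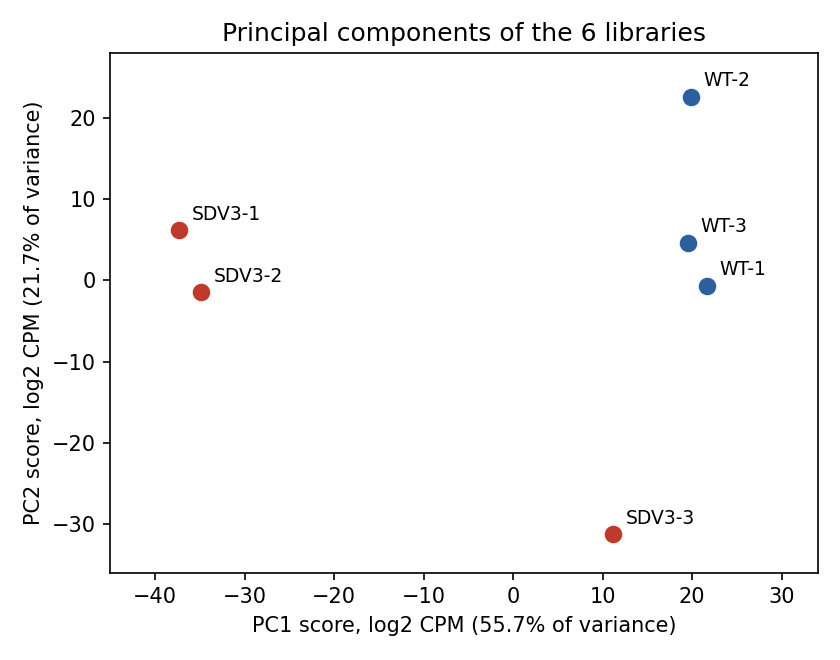
Principal component scores of the 6 libraries from log2 CPM, SDV3 in red and WT in blue, with the share of variance on each axis. SDV3-3 sits at 11.1 on the leading component, nearer to the WT libraries than to SDV3-1 and SDV3-2.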

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

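The fit that includes the unannotated and sRNA features was chosen after seeing the data, and the test against the genes opposite was planned before its result was seen. The unannotated and sRNA features of the deposited table are outside the comparison of the report, and 8 of them were higher in SDV3 and 1 was lower when 375 such features were tested by edgeR beside the annotated genes (Benjamini-Hochberg adjusted p under 0.05). A signal in data that the report's comparison does not use drew attention to them. All 9 lie opposite annotated genes. Their median absolute difference in log2 fold change from the genes opposite was 0.418, under the bound of 0.5 fixed for reads of those genes counted on the feature. Over all 366 such features with a tested gene opposite, called or not, the median was 0.642. The value for the 9 is what reads of the opposite genes would give, but single features differ by up to 1.19, and a real antisense transcript that follows its gene was not tested.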

How the results depend on the processing

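The 3 alternatives with unannotated and sRNA features, with stable RNA genes left out and with a robust fit were chosen after seeing the data. DESeq2 called 463 genes, 339 with a fold over 2, and camera with an estimated correlation called 0 lists; the cause was not tested. Leaving out 1 library gave 2 to 1327 genes, 2 to 757 genes with a fold over 2 and 9 to 11 lists. Without SDV3-3 it was 1327 genes, without SDV3-1 29, without SDV3-2 11, without WT-1 2, without WT-2 7 and without WT-3 2. The alternatives other than DESeq2 that kept all libraries called 32 to 54 genes. With the library number as a block, used as a check since the numbers do not pair the samples, 32 genes passed, 28 of them among the 40.

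The 40 called genes kept their direction in every alternative that tested them (ffs is removed where the stable RNA genes are left out). Of the 25 called named genes, 23 missed the threshold in at least 1 leave-one-out fit and 3 (HRJ35_RS17230, HRJ35_RS05050 and metE) in another alternative. mtrC passed in 2 alternatives. Of the 10 called lists, 9 stayed past the threshold in each alternative with the preset correlation and all libraries, and 6 in each leave-one-out fit. Without SDV3-3 the list for shikimate and aromatic synthesis passed (camera adjusted p = 0.0199, against 0.122 with all libraries). The list for branched-chain amino acids passed there too (camera adjusted p = 0.0137, against 0.135).

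Of the 10 splits of the 6 libraries into 3 and 3, 1, the real split itself, gave as many genes (40, highest other 4), and 1 as many with a fold over 2 (40, highest other 4). For the gene counts, a share under 0.05 cannot be reached with 10 splits. For the lists, 4 splits, the real one among them, gave at least as many (10, highest other 13). The number of lists therefore did not set the real split apart from other splits.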

Other observations

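In this part the exchange test, the mixture test and the test on large changes were chosen after the results were seen. The bounds of the exchange and mixture tests were also revised after their values were seen. SDV3-3 lay apart from SDV3-1 and SDV3-2, and correlated with each WT library (Pearson r = 0.929 to 0.951) more than with either of them (0.904 and 0.918). In the planned test of a wrong label, the lowest share of genes at which SDV3-3 lay beyond the WT libraries was set against the highest share of a left-out WT library. It was higher by 5.74 percentage points, between the bounds of 5 and 20 fixed for that test. These 2 shares come from different gene sets. Within each set SDV3-3 had the higher share, at 61.0% against 49.9% with WT-1 left out, 55.6% against 43.6% without WT-2 and 56.3% against 42.7% without WT-3. A test on changes of at least 2 on the log2 scale, with genes chosen without SDV3-3, gave 7.82 points, between the same bounds. That value comes from the set without WT-2, at 27.9% for SDV3-3 against 20.1%. The shares were 32.9% against 2.86% without WT-1 and 35.7% against 14.9% without WT-3. With a WT library in the place of SDV3-3, edgeR called 0, 4 and 0 genes against 40, a difference of 36 from the highest. If SDV3-3 were a WT library, these 4 arrangements would be interchangeable, so the real one would be highest in 1 of 4 cases. Single genes lie far on the SDV3 side in SDV3-3, such as sirA at 719 CPM (18.0 to 24.7 in WT) and HRJ35_RS18340 at 11.4 CPM (121 to 155 in WT), which goes against a WT library. Both also pass without SDV3-3 (sirA log2 fold change 4.10, edgeR adjusted p = 0.00563; HRJ35_RS18340 -3.13, edgeR adjusted p = 0.00183), as do all 40 called genes. That fit calls 1327 genes, though, and the 40 are those that pass with SDV3-3 as well, so the tests on whole sets chosen without it were used. By their bounds these leave a wrong label open, with SDV3-3 above the left-out WT library in each set.

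A mix of the RNA of the other libraries would lie within their range. SDV3-3 lay at least 2-fold outside that range at 62 genes, with napA, napB, napG and napH at 5.56 to 7.91 times the highest other library, which such a mix would not give. WT-2 lay outside at 61 genes, so departures of this number also occur in a library that is not between the strains, and a mix with other SDV3 or WT cells stays open. The log2 ratio of SDV3-3 to the other SDV3 libraries had a Spearman rho of 0.128 with gene length over 4090 protein genes. This is a weak relation, between the bounds of 0.1 and 0.3, so the test did not decide on uneven recovery of short transcripts. Short RNA genes went both ways, with a lower share of counts on tRNA genes and a higher share on ssrA and rnpB in SDV3-3 than in SDV3-1 and SDV3-2. No biological explanation was tested.

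The genes named here were chosen after their values were seen, and napA, argG and thiC stood far above all other libraries in a single library. napA had 5229 CPM in SDV3-3 against at most 941 elsewhere, and was also higher in SDV3-1 and SDV3-2 than in each WT library. argG had 2153 CPM in WT-1 against at most 249, and thiC had 1210 CPM in WT-2 against at most 132. putP had 1035, 1103 and 86.8 CPM in SDV3-1, SDV3-2 and SDV3-3 and 24.4 to 55.7 CPM in WT (edgeR adjusted p = 0.0752).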
